A study of Mus musculus with 6 samples.

How the data were processed

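Brains of 3 wild type and 3 Neil3 knockout male mice aged 3 to 6 months were frozen, cut at 8 µm, and CA1 was isolated by laser microdissection. Per the labels' protocols, DNA was sonicated to about 250 bp, ligated to methylated adaptors, bisulfite converted, size selected, amplified and sequenced on an Illumina instrument. The labels give the molecule as RNA, although the protocol and the series type describe bisulfite sequencing of DNA. Bisulfite treatment turns unmethylated cytosine into uracil and leaves methylated cytosine, so the share of reads that keep a cytosine is the methylation level. It does not separate 5-methylcytosine from 5-hydroxymethylcytosine, which is abundant in brain.

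Reads were aligned with BSMAP, and GRCm38 (mm10) was the genome, per the submitters' processing notes. The region caller, its settings, its coverage minimum and its treatment of CpGs without reads are not given in the sources used here. The authors' deposited table holds 230 called CG regions. Their levels are fractions from 0 to 1, given by the authors as a mean per group. A q-value per region was deposited by the authors, at most 0.0475, with the adjustment method not given in the sources used here. The deposited table also gives the number of CpGs, at least 10 per region, and a difference of the group means whose size is at least 0.101. The second deposited table lists 36 genes with their bounds, transcription starts and GC content in percent, the last of which was not used. The group order comes only from the sheet title, which names wild type before the knockout. Differences are printed here as knockout against wild type. The difference equalled the first mean minus the second within 0.001 in 213 regions and not in 17. In 1 of these, at 90761688 to 90762378 on the Y chromosome, it had the opposite sign. The direction of a region was taken from the deposited difference, with the sign of the difference of means as an alternative. The last column of the table holds 4 words beside its first lines, read as a colour legend and not used. Whether positions count from 0 or 1 is not given in the sources used here, so bounds may be off by 1 base.

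The table gives neither values per animal nor coverage. The depth is therefore unknown, no region was tested again, and no spread between animals was computed. The planned permutation test per region was not run for this reason. Intervals of shares are 95% Wilson intervals over regions and cover counting error only.

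Regions were placed on genes of the RefSeq annotation of GRCm38.p6, the same build. All 36 listed gene symbols matched. The annotation used has gene bounds without exons, strands or chromosome lengths, so exons and introns were not analysed here, and the assembled length of chromosomes was replaced by the number of genes or by the stretch from the first to the last gene. Of the annotation, 49603 genes were used, and 340 placed under 3 Mb on chromosomes other than Y were left out because those positions belong to scaffolds. Starts of transcription were taken from the second deposited table, so windows around starts cover its 36 genes only. The strand was inferred from whether starts lay at the lower or the upper bound of the gene.

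Directions were tested with exact binomial tests against an even split and with Fisher's exact test. Sizes were compared with a permutation test of the difference of medians (100000 resamples). Positions were tested against 10000 random placements of regions of the same lengths, on the whole genome for the count near Neil3 and on the same chromosome for gene overlap and gene lists. CpG density was not matched. Counts per chromosome were tested with exact binomial tests against the number of genes. Adjusted p-values are Benjamini-Hochberg values over 21 chromosomes, 20 lists or 2 correlations. The interval around Neil3 joins regions of chromosome 8 less than 2 Mb apart and was defined after seeing the data. The gene lists and the rule for named regions were fixed before the data were examined. Named were the 12 largest gains and the 12 largest losses, regions in genes of the fixed lists, the 10 regions nearest to Neil3 and up to 10 genes with at least 2 regions. The text gives part of these. Other genes in the text were named after their values had been seen. The groups of neighbouring regions outside chromosome 8 were also described after seeing the data.

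The placement test near Neil3 was tested on simulated data. With 230 regions placed at random in 500 simulations, 3% gave a p under 0.05, and with 20 regions planted in the window all of 200 simulations (100%) were called. The simulated regions were placed independently, in the same way as the placements of the test itself. The simulations therefore check the code only and do not give the rate of false calls for clustered regions. Alternatives were other limits on the difference, CpG number and q-value, merging of regions within 10 kb, autosomes only, genes as units, other windows, other overlap rules, protein-coding genes only, genes extended by 5 kb, and leaving out chromosome 8. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.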

Results

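CpG methylation was measured by whole-genome bisulfite sequencing in the CA1 field of the hippocampus, cut out of frozen brain sections by laser microdissection. The DNA came from 3 wild type male mice and 3 male mice lacking NEIL3, a DNA glycosylase that removes oxidised bases in the base excision repair pathway. Both groups were on a C57Bl6 background and were taken from the home cage without any intervention. The comparison asked what the loss of NEIL3 does to DNA methylation in CA1 at rest. The authors' deposited table lists 230 regions called as differentially methylated in the CG context, with a mean level per group and a q-value per region. It gives no value per animal and no coverage, so the depth behind each level is unknown and no spread between animals could be given. Wild type is taken as the first group and the knockout as the second from the sheet title alone.

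Methylation was lower in the knockout in 163 of the 230 regions and higher in 67, by the sign of the difference in the authors' deposited table. The share that was lower was 70.9% (95% Wilson interval 64.7% to 76.4%), which differed from an even split (exact binomial p = 2.06e-10, two-sided, regions as units). This excess came from chromosome 8, the chromosome that carries Neil3, where 112 regions were lower and 6 were higher. On the other chromosomes 51 regions were lower and 61 were higher, and the share of 45.5% (95% Wilson interval 36.6% to 54.8%) did not differ from an even split (exact binomial p = 0.395). The 230 regions held 8363 CpGs, with a median of 26 CpGs and 469.5 bp per region. Regions are the units of these tests, which describe the authors' list and not the variation between the 6 animals.

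Chromosome 8 held 118 of the 230 regions, or 51.3% (95% Wilson interval 44.9% to 57.7%), against 11.04 expected from its share of annotated genes. That is 10.7 times the expected number (exact binomial p = 8.30e-91, adjusted p over 21 chromosomes 1.74e-89). The Y chromosome held 19 regions against 1.80 expected from its genes (exact binomial p = 5.84e-14, adjusted p = 6.13e-13). From the stretch its genes span, 7.85 were expected (exact binomial p = 0.000398, adjusted p = 0.00209). These tests take regions as independent, but 15 of those on Y lay within 0.111 Mb, and 114 of those on chromosome 8 in 1 interval. Chromosome 19 held 0 regions, chromosome 10 held 1 and chromosome 1 held 3. The expected numbers share out all 230 regions, so the excess on chromosome 8 leaves fewer than these for the other chromosomes together.

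**Figure D1:**
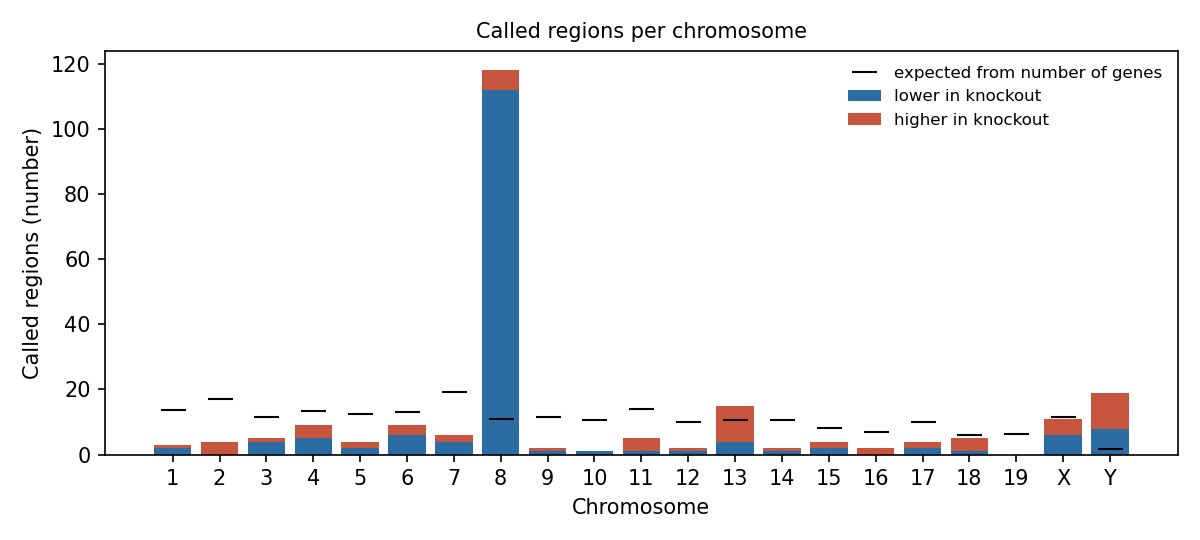
Number of called regions on each chromosome, split into regions lower (blue) and higher (red) in the Neil3 knockout. Black dashes mark the number expected when all 230 regions are shared out by each chromosome's annotated genes, and chromosome 8, with 118 regions of which 112 were lower, stands above all others.

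On chromosome 8, 114 of the 118 regions lay in a single interval from 47003301 to 60851601 (GRCm38), 13.8 Mb long, with Neil3 at 53586867 to 53639065 inside it. Of these, 110 were lower in the knockout and 4 were higher. The median of the authors' means in the interval was 0.862 in wild type and 0.108 in the knockout, and in 54 of the 114 regions the knockout mean was under 0.1. Within 10 Mb of Neil3 there were 114 regions, whereas 10000 random placements of the regions on the genome gave a mean of 1.74 and at most 9 (one-sided permutation p = 0.0001, the smallest that 10000 placements can give). The counts were 92 within 5 Mb and 115 within 20 Mb. The random placements took each region as independent. The p-value therefore does not measure how unusual a cluster of regions at Neil3 is.

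Inside Neil3 itself the authors' deposited table lists 3 regions, all lower in the knockout. At 53607982 to 53609713, with 32 CpGs, the authors' mean was 0.845 in wild type and 0.00347 in the knockout (q = 5.27e-22 in the authors' deposited table). The region at 53604478 to 53605751 went from an authors' mean of 0.907 in wild type to 0.140 in the knockout (q = 1.21e-27 in the authors' deposited table). The region at 53603378 to 53603816 differed less, from 0.909 to 0.695 (q = 0.0264 in the authors' deposited table). The next 7 regions by distance lay 250638 to 623846 bp from the gene, and all were lower in the knockout, such as the region at 53334025 to 53336229 with authors' means of 0.839 and 0.204. With levels given per group only, the targeted locus could not be checked in single animals. Neil3 is the disrupted gene, and coverage is not given. Sequence missing from the knockout therefore cannot be told apart from lost methylation in these 3 regions.

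All 12 of the largest losses lay in this interval, with sizes from 0.862 to 0.926 in the authors' deposited table. Without coverage, reads missing from the knockout cannot be told apart from lost methylation in any region of the interval. The largest was a region at 55502079 to 55502466 that overlapped no annotated gene, with authors' means of 0.938 in wild type and 0.0127 in the knockout. The next was in Gpm6a, which encodes a neuronal membrane glycoprotein, at 54868254 to 54868708, where the authors' mean was 0.928 in wild type and 0.00629 in the knockout (q = 7.60e-39 in the authors' deposited table). A region of Tenm3, a teneurin that guides hippocampal wiring, at 49016747 to 49017065 had authors' means of 0.922 and 0.00280. Several genes of the interval carried many regions. Tenm3 had 10, of which 9 were lower and 1 was higher. Galntl6, of the family of enzymes that start O-linked glycosylation, had 8 regions and all were lower, with knockout means in the authors' deposited table of 0.0119 to 0.213. Stox2 had 4 lower regions and 1 higher region, and Enpp6, a choline phosphodiesterase made by oligodendrocytes, had 4 lower regions with the authors' knockout means between 0.0340 and 0.229. The long noncoding RNA gene 1700019L22Rik had 2 lower regions. Gene length was not allowed for in these counts, and the interval held 8.23 regions per Mb. At that density the counts in Tenm3 (48225665 to 49522824) and Galntl6 (57772489 to 58912531) were no higher than their lengths would give. Those in the shorter genes Stox2 and Enpp6 were higher, and that in 1700019L22Rik was lower. The higher region of Stox2, at 47303999 to 47304368, had authors' means of 0.220 in wild type and 0.867 in the knockout.

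**Figure D2:**
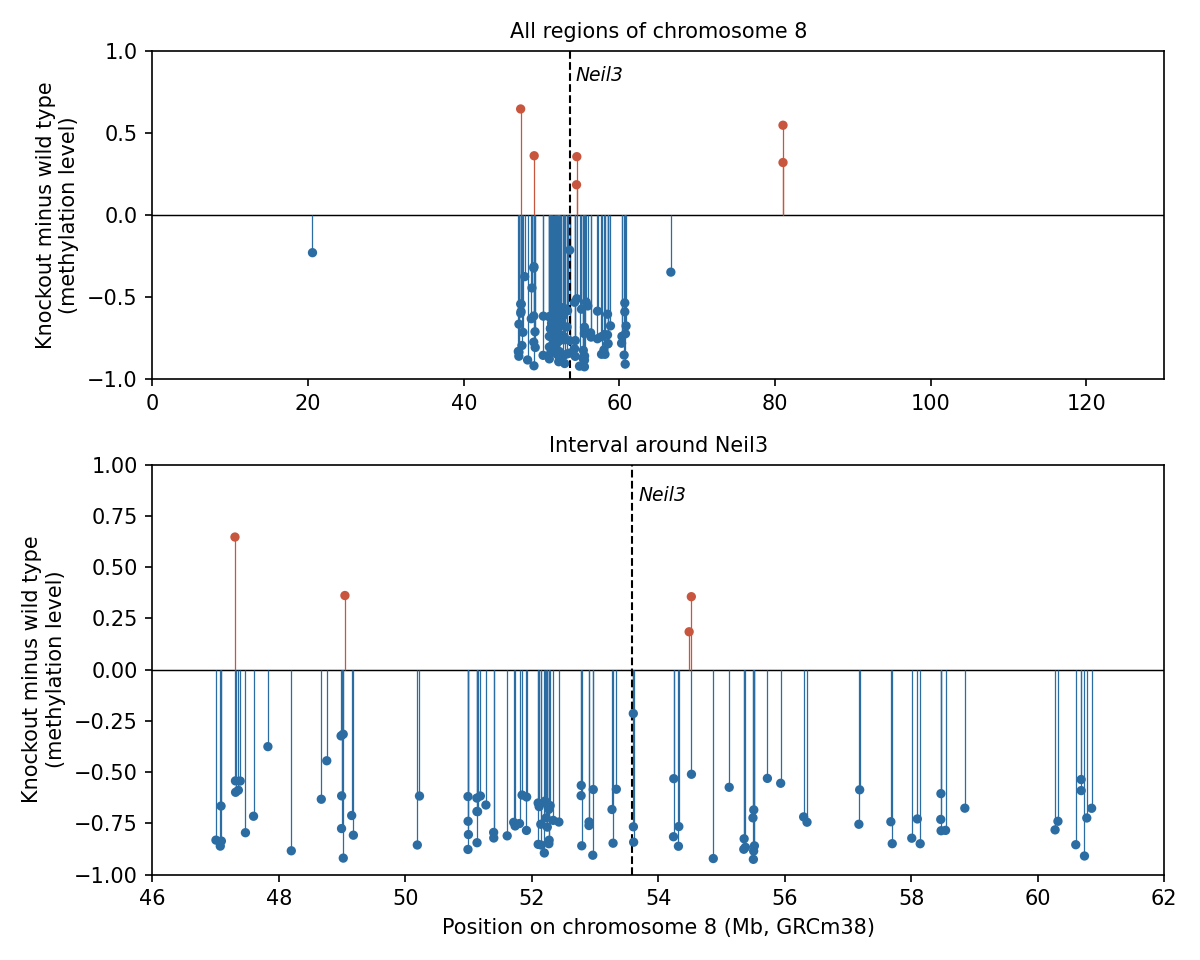
Knockout minus wild type methylation level (a fraction) of each called region against its position on chromosome 8 in Mb, over the whole chromosome (top) and over the interval around Neil3 (bottom). Blue points are lower and red points higher in the knockout, each point is 1 region, the dashed line marks Neil3, and 114 of the 118 regions fall between 47003301 and 60851601.

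Outside chromosome 8 the median of the authors' means over the 61 regions that were higher in the knockout was 0.167 in wild type and 0.712 in the knockout, and over the 51 regions that were lower it was 0.787 in wild type and 0.358 in the knockout. The largest gain of all was in Rims2, a scaffold protein of the presynaptic active zone, at 39244206 to 39244894 on chromosome 15, where the authors' mean was 0.0118 in wild type and 0.880 in the knockout (q = 8.90e-15 in the authors' deposited table). Rims2 held another higher region at 39246722 to 39247057, with authors' means of 0.133 and 0.746. Rbfox1, a neuronal splicing regulator on chromosome 16, had authors' means of 0.0389 and 0.779 at 6121713 to 6122133. Immp2l, a subunit of a mitochondrial inner membrane peptidase on chromosome 12, had authors' means of 0.0988 and 0.916 at 41305466 to 41306183. Among the 61 higher regions outside chromosome 8, 22 had a wild type mean under 0.1. Without coverage, it cannot be told whether reads were missing where levels were this low. Of the 12 largest gains, 3 were on the X chromosome and 3 on the Y chromosome, and their sizes in the authors' deposited table ran from 0.670 to 0.868. Over all 230 regions the median size was 0.641 for losses and 0.441 for gains in the authors' deposited table (permutation p = 8.00e-05, two-sided). Without chromosome 8 the order turned, with medians of 0.305 for losses and 0.442 for gains in the authors' deposited table (permutation p = 0.00442).

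**Figure D3:**
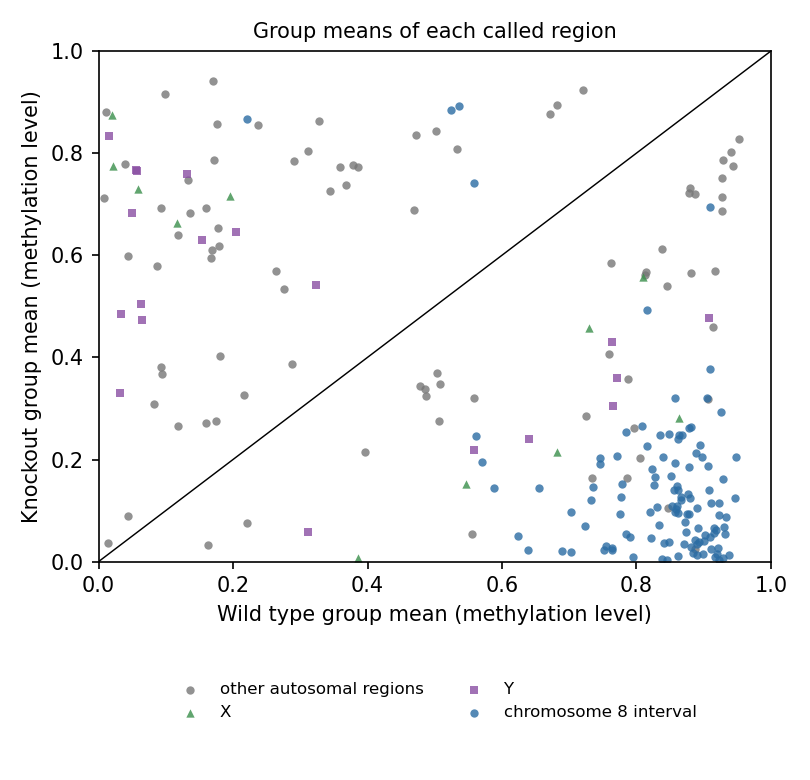
The authors' mean methylation level (a fraction) of each called region in wild type (horizontal) and in the Neil3 knockout (vertical). Points below the diagonal are lower in the knockout, where regions of the chromosome 8 interval (blue circles) crowd at the lower right, with medians of 0.862 and 0.108, and other autosomal, X and Y regions lie on both sides.

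Away from chromosome 8 there were further groups of neighbouring regions. On chromosome 13, 10 regions between 65762042 and 66418825 were all higher in the knockout, with median authors' means of 0.336 in wild type and 0.780 in the knockout. They included 3 regions in Vmn2r-ps98, a pseudogene of the vomeronasal receptor family, where the authors' knockout means were 0.610 to 0.863. At the distal end of the Y chromosome, 15 regions between 90718204 and 90829294 were mixed, with 7 lower and 8 higher by the deposited difference. The region at 90761688 to 90762378, counted as lower, had authors' means of 0.324 in wild type and 0.541 in the knockout. All 4 regions overlapping the predicted gene Gm52481 there were lower in the knockout, with median authors' means of 0.769 and 0.332. Deposited differences and means did not match in most of these. At 90744877 to 90745560 the difference was 0.564 in size beside means of 0.766 and 0.304. On the X chromosome both regions in Mid1, a gene that crosses the pseudoautosomal boundary in mice, were lower. The one at 169987051 to 169987430 had authors' means of 0.385 and 0.00774. The other, at 169987628 to 169988560, had a deposited difference of 0.525 in size beside means of 0.809 and 0.557. The ribosomal DNA copy at Rn18s-rs5 on chromosome 17 had the region with the most CpGs, 490, and the smallest q-value in the authors' deposited table, 2.04e-163, for a change in the authors' mean from 0.175 to 0.276. Read mapping was not analysed here for any of these groups, so reads shared between copies were not excluded.

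The 12 gene lists and 8 cell type marker lists fixed before the data were examined held 7 genes with a region, against a mean of 7.43 in random placements. The placements spread the clustered regions of chromosome 8 over that whole chromosome, and without chromosome 8 the lists held 6 genes against a mean of 4.23. Of the 20 lists, 14 held no gene with a region. These were DNA methylation and demethylation, glutamate receptors, GABA receptors and synthesis, immediate early genes, voltage-gated channels, axon guidance and cadherins, neurogenesis, and the markers of CA1 neurons, CA3 and CA2 neurons, dentate granule cells, astrocytes, oligodendrocytes, microglia and vessels. Random placements gave a mean of 3.39 genes for axon guidance and cadherins and 1.14 for voltage-gated channels (1.37 and 0.728 without chromosome 8), and 0.373 or fewer for each of the other empty lists, so 0 was the likely count in those. Among base excision repair genes, 1 of 25 held a region, and that gene was Neil3 (one-sided placement permutation p = 0.0917, adjusted p = 0.611). Of 32 postsynaptic density and plasticity kinase genes, only Camk2b, a subunit of the calcium/calmodulin-dependent kinase of synaptic plasticity, held regions, against 0.814 genes in random placements and 0.296 without chromosome 8 (permutation p = 0.642 and 0.260, adjusted p = 1 in both). Both of its regions were higher in the knockout. At 6006638 to 6007141 on chromosome 11 the authors' mean was 0.178 in wild type and 0.653 in the knockout (q = 1.61e-32 in the authors' deposited table). Of 35 presynaptic and adhesion genes Rims2 alone held regions (permutation p = 0.377, adjusted p = 1). Erbb4, a neuregulin receptor, was the 1 of 17 interneuron markers with a region (permutation p = 0.0372, adjusted p = 0.372), at 68625056 to 68625300 on chromosome 1, with authors' means of 0.881 and 0.565. Of 2076 olfactory, vomeronasal and Skint family genes, Vmn2r-ps98 alone held regions (permutation p = 0.396, adjusted p = 1). None of the 20 lists passed at an adjusted p of 0.05 in the placement permutation test, and 2 had an unadjusted p under 0.05.

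The imprinted genes gave the lowest p among the lists. Of 37 of them, 2 held a region against 0.0939 in random placements (one-sided permutation p = 0.00730, adjusted p over 20 lists 0.146). Both are expressed from the paternal copy only, and both regions were lower in the knockout. In Peg10, at 4747293 to 4747624 on chromosome 6, the authors' mean was 0.485 in wild type and 0.337 in the knockout (q = 1.51e-06 in the authors' deposited table). In Peg3, at 6729846 to 6730263 on chromosome 7, it was 0.508 in wild type and 0.349 in the knockout (q = 1.69e-07 in the authors' deposited table). With genes extended by 5 kb on each side, 4 imprinted genes held a region and the adjusted p was 0.0020. The 4 genes rest on 3 regions, because the region in Peg10 also counts for its neighbour Sgce. The other additional gene was H19, whose nearest region lay 2601 bp away at 142580747 to 142581071 on chromosome 7 with authors' means of 0.503 and 0.369. The placements did not match CpG density, so these p-values are not tests against sequence where regions could be called.

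Of the 230 regions, 102 overlapped an annotated gene, 44.3%, against 44.8% (95% range 38.7% to 50.9%) in 10000 random placements on the same chromosomes (two-sided permutation p = 0.939). Without chromosome 8 the share was 50.9% against 40.2% in placements (permutation p = 0.0174). In the interval around Neil3 it was 37.7% against 49.2% in placements (permutation p = 0.0164). Both settings were chosen after seeing the data. The share over all regions thus combines departures in opposite directions. The placements did not match CpG density, which was 8.52 CpGs per 100 bp in regions outside chromosome 8 and 3.81 in regions of the interval. Gene overlap was less frequent among lower regions, 63 of 163, than among higher regions, 39 of 67 (Fisher's exact p = 0.00846, two-sided), but without chromosome 8 it was 23 of 51 against 34 of 61 (Fisher's exact p = 0.343).

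The second table of the authors lists 36 genes, and 35 of them had a region within the bounds it gives. The remaining gene, Gpm6a, had its region within the bounds of the RefSeq annotation. Within the bounds of that table the listed genes held 55 regions, of which 32 were lower and 23 higher in the knockout, a smaller share of lower regions (58.2%) than the 74.9% among the other regions (Fisher's exact p = 0.0262, two-sided). This call rested on those bounds. With regions in the RefSeq bounds of the listed genes counted as well, which adds 8 of the 10 regions of Tenm3 and that of Gpm6a, the shares were 62.5% of 64 regions and 74.1% (Fisher's exact p = 0.105). Without chromosome 8 they were 29.6% and 50.6% within the bounds of the table (Fisher's exact p = 0.0760). Between 2 kb upstream and 0.5 kb downstream of an annotated start of a listed gene lay 11 regions, 5 lower and 6 higher (Fisher's exact p = 0.0844 against all other regions). Without chromosome 8 these were 4 lower and 5 higher (Fisher's exact p = 1). The genes with a higher region there were named after their values had been seen. One was the chemokine gene Cxcl1, with authors' means of 0.0831 in wild type and 0.308 in the knockout, and another was the complement regulator Cd59a, with authors' means of 0.276 and 0.534. The others were Cdk5rap1, Zc3h7a, Hnrnpa3 and Usp38. The 5 lower regions lay at starts of Peg10, Peg3, Cldn22, Eif2s3y, and Tmem267 together with 3110070M22Rik. For Hnrnpa3 the authors' deposited table gives a difference of 0.321 in size beside group means of 0.0144 and 0.0371, so its size is uncertain, and for Usp38 it gives 0.320 beside 0.0436 and 0.0885.

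Across the 230 regions, those with more CpGs had smaller differences in the authors' deposited table (Spearman's rho = -0.433, permutation p = 1e-05, adjusted p = 2e-05; Pearson's r = -0.346, permutation p = 1e-05, the smallest that 100000 resamples can give). Without the 2 regions farthest from the median number of CpGs, r was -0.379. For region length the relation was weaker (rho = 0.152, permutation p = 0.0213, adjusted p over both relations 0.0213; r = 0.0555, permutation p = 0.403), and r was 0.125 without the 2 regions of most extreme length. Without chromosome 8, rho for length was -0.0043 (permutation p = 0.964). These are correlations across regions, which are not independent replicates. Only called regions are listed, and a region with few CpGs may need a large difference to be called. The relation with CpG number may therefore reflect the calling limits.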

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

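Chosen after seeing the data were leaving out the interval around Neil3, leaving out chromosome 8 in all but the direction count, autosomes other than chromosome 8, the sign of the difference of means, the RefSeq bounds of listed genes, the gene-bearing stretch as background, and the settings for the share of regions on chromosome 8. Of 55 recomputed values, 37 kept their direction and their side of the threshold, or stayed close to the first value where there was no test. The share of lower regions was 65.8% to 74.5% under the limits on difference, CpGs and q-value, on autosomes and with neighbouring regions merged. It turned to 45.5% without chromosome 8, 45.7% without the interval around Neil3 and 45.1% on autosomes other than chromosome 8, because the lower regions removed lie there. Counting each gene once gave 53.6% (exact binomial p = 0.630), but this setting also leaves out regions outside genes, and of the 102 regions overlapping a gene 63 were lower. Losses minus gains in median size was 0.45 with log2 ratios of the levels in place of differences (permutation p = 0.0665), and -0.137 without chromosome 8. The share of regions on chromosome 8 was 61.2% with a difference of at least 0.3 and 59.0% on autosomes. Gene overlap minus that of random placements was -0.469 percentage points at first and 10.7 without chromosome 8. The correlation with region length was -0.0043 without chromosome 8. The share of lower regions in the listed genes was 29.6% without chromosome 8 (Fisher's exact p = 0.0760) and 62.5% with their RefSeq bounds (Fisher's exact p = 0.105). With genes extended by 5 kb, 1 list, the imprinted genes, passed where 0 had before. The clustered receptor families held 0 genes with a region among protein-coding genes only, and base excision repair held 0 without chromosome 8, each below its placement mean in place of above it, because Vmn2r-ps98 is a pseudogene and Neil3 lies on chromosome 8. For starts of listed genes the count was 7 with a window of 1 kb upstream and 15 with 5 kb upstream to 1 kb downstream (Fisher's exact p = 0.0147, past the threshold, but p = 1 without chromosome 8, with 5 lower and 7 higher). Where not stated, the cause was not tested. The limit of 10 CpGs removed no region and says nothing about stability. No paired analysis was possible because the deposited table has no values per animal, although the labels share the numbers 2 and 3, and leaving out single animals was not run for the same reason. Background by CpGs per chromosome was not run either. Depth could not be weighed, since no coverage was used here.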

Other observations

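Of the tests in this part, the direction count without chromosome 8 and the count within 10 Mb of Neil3 were fixed before the data were examined. The share of knockout means under 0.1 and the tests on chromosome 13 and on intermediate levels were chosen after the patterns had been seen. A few regions outside the groups above were lower in the knockout from a wild type level near 0.5. They included Dppa3, whose product guards methylation in the zygote, at 122627432 to 122627770 on chromosome 6, with authors' means of 0.559 in wild type and 0.320 in the knockout. Eml1, a microtubule-binding protein, had authors' means of 0.479 and 0.345 at 108509031 to 108509365 on chromosome 12. Among genes that were higher, Neo1, a receptor of netrins and repulsive guidance molecules, had authors' means of 0.291 and 0.785, and Tmem132d had 0.0924 and 0.692. Pik3c3, the class III phosphoinositide 3-kinase, held 2 higher regions with median authors' means of 0.105 and 0.511.

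The interval on chromosome 8 is the widest pattern in the list. On the other chromosomes 45.5% of the called regions were lower and the upper Wilson bound was 54.8%. This argues against a general lean of called regions towards loss. No genome-wide level was used here, so a loss too small to be called as a region cannot be excluded. Sequence of the embryonic stem cell strain kept around the targeted gene may account for the interval. So may a local effect of the missing gene on its neighbourhood. Both predict an excess close to Neil3, where 114 regions lay within 10 Mb against 1.74 in random placements (one-sided permutation p = 0.0001, the smallest possible). The placements took each region as independent, although the regions of the interval are clustered. The count within 10 Mb does not separate these explanations. Strain differences that remove CpGs or stop reads from aligning could then be read as lost methylation, and knockout means under 0.1 made up 47.4% of the interval, but without coverage this cannot be told apart from true loss. Genotypes along chromosome 8 were not analysed here.

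The 10 regions of the chromosome 13 group were all higher in the knockout. Of the 27 genes in that stretch, 96.3% are pseudogenes or predicted genes, at the 96.6th percentile of 7775 random intervals of its length with at least 5 genes, whose median was 52.4%. Reads shared between near-identical copies, or a different number of copies between the groups, may therefore shift these levels. A biological gain at these genes stays open, because read mapping was not analysed here.

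The regions in or near the imprinted genes Peg10, Peg3 and H19 were lower in the knockout by similar amounts, 0.148, 0.160 and 0.134 in the authors' deposited table. A loss at sites methylated to an intermediate level might produce this. Outside chromosome 8, 9 of 13 regions with a wild type level of 0.4 to 0.6 were lower, against 42 of 99 others (Fisher's exact p = 0.0816, two-sided). This test cannot decide the question, because the wild type level also limits the direction a region can take. With a wild type mean under 0.1, 22 regions outside chromosome 8 were higher and 0 were lower. Since 3 of the 9 are the imprinted regions themselves, the test is not independent of the pattern. Whether 1 animal drives these levels cannot be told from group means.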
